A study of Sorghum bicolor with 8 samples.

How the data were processed

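RNA was extracted from 3 types of sorghum callus and from leaves, and 8 libraries were sequenced on an Illumina instrument, with 2 biological replicates in each of 4 groups per the labels. Callus is unorganised plant tissue grown in culture. Here it came from immature embryos of the wild-type line Hiro-1, 1 to 2 mm long and taken 13 to 15 days after flowering. The embryos were kept for 3 weeks on induction medium in the dark at 25 °C, after which the callus types were separated and subcultured for 20 days. The leaves had grown from Callus II on differentiation medium, under 16 h of light at 2000 lx and 8 h of dark.

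The deposited values are FPKM (fragments per kilobase of transcript, scaled to the number of fragments sequenced), as the file headers name them, with a gene identifier and a locus for each of 34129 genes. The submitters' processing notes name Trimmomatic, TopHat2 2.0 and Cuffdiff, with no roles. The genome build, the settings and any filters are not given in the sources used here, and neither is whether strand was used in counting. All files held the same genes and loci in different row orders and were joined by identifier. Of the 34129 genes, 3621 were at 0 in all 8 libraries and 20136 were above 0 in all 8. The loci of 4052 genes (11.9%) overlapped another locus, so reads may have been shared between them.

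Locus starts in the files count from 0. After 1 was added, 884 starts equalled a gene start in an NCBIv3 gene table, against 345 with no change, and 806 ends were equal with no change. The coordinates printed are those of the files with 1 added to the start. None of the identifiers was found in that table of 32945 genes (0 matched), and the files do not pair identifiers with names. Genes are therefore given by identifier, with at most 2 that rose and 2 that fell in each comparison. The 29 gene lists fixed for this tissue, which needed gene descriptions, had 0 members, and the gene list tests were not run.

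No library held values identical to another. The sum of FPKM per library ran from 595109 to 737291. Read totals are not given, so the absolute depth is unknown. Some ratios of values under 0.2 FPKM between libraries fell on steps that a whole fragment would give. Against Callus I replicate 1, such ratios made up 50.3% to 56.7% of low pairs in the callus libraries. In Leaf they made up 22.0% and 26.6%, and most lay off the steps. These shares are the highest over a grid of step positions, and the median over the same grid was 0.4% to 1.0%. The step size gave an estimate of the depth relative to Callus I replicate 1, which was 1.028 for Callus I replicate 2, 1.075 and 0.973 for Callus II, 0.966 and 0.997 for Callus III, and 1.27 and 1.625 for Leaf. The Leaf estimates were the highest and rest on a minority of pairs. The settings of Cuffdiff are not given, so the step may also hold its scaling of the libraries. If the Leaf estimates hold, genes of low abundance could be detected more easily in Leaf.

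Genes with at least 1 FPKM in at least 2 of the 8 libraries were tested, 23166 in all. Values were taken as log2(FPKM + 1) and fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group over all 8 libraries, moderated variances with a trend (prior degrees of freedom 2.83) and 2-sided tests. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. No fold is given against a group listed at 0, because a 0 in these files can be a failed estimate. The p-values measure the spread between 2 libraries per group. The labels call them biological replicates and do not say whether they came from separate cultures, so part of that spread may be technical. A permutation test of 2 libraries against 2 cannot give a 2-sided p below 0.333, so every call rests on the variance shared across genes and groups.

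The 5 comparisons, their tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took called genes with both libraries of one group above both of the other and a mean of at least 10 FPKM in the higher group, ordered by log2 change, and the largest 2 in each direction are printed. The rule also asked for a known gene description, and that part could not be applied because no descriptions were paired with the identifiers. For Callus II against the mean of the other callus types, the gene also had to be called with the same sign against each. On simulated values for Callus II against Callus I with 23166 genes and 200 changed, the test recovered 47% of changes of 1 and 86% of changes of 2 on the log2 scale. Of its 140 calls, 7 (5%) were false. In the data 14936 genes were called in this comparison, which makes the adjusted threshold less strict. The simulated shares are therefore not those of the reported calls.

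After it was seen that the genes had no names, the order of genes along the chromosomes was used. A run was at least 5 tested neighbours called in the same direction with an absolute log2 change of at least 1. Genes that failed the filter were left out of the order, so a run may span untested loci with low values. Runs were counted again in 1000 shuffled gene orders. Chromosome shares were compared with 1000 random rotations of the gene order, which keep neighbours together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps, and matplotlib 3.10.9 for the plots.

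The alternatives were a pseudocount of 0.1 FPKM, no filter on low values, a mean of at least 5 FPKM, median-ratio scaling of the libraries, other variance priors, a replicate block, each library left out in turn, a fold threshold, and a fit to fewer groups. Added after the data were seen were loci of at least 500 bp only, equal sums of FPKM without the 100 highest genes, and median-ratio scaling together with the fold threshold. Counts of genes at 0 in both libraries of one group and at 10 FPKM or more in both of the other were taken from the values with no test, and such a count often rises when a library is left out.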

Results

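The transcriptomes of Callus I, Callus II, Callus III and regenerated Leaf of sorghum were compared. The series concerns callus types with different capacities for regeneration. The labels do not rank these capacities, and they state only that the leaves grew from Callus II. Each group had 2 libraries. Genes above 0 numbered 25863 and 24760 in Callus I, 24500 and 24497 in Callus II, 24816 and 25451 in Callus III, and 26617 and 26787 in Leaf.

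The 4 tissues had clearly separate expression profiles, and Callus III was the callus type nearest to leaf. Across 23166 genes, the Pearson correlation of log2(FPKM + 1) between replicates was 0.975 in Callus I, 0.984 in Callus II, 0.982 in Callus III and 0.993 in Leaf. Leaf correlated at 0.62 ± 0.001 with Callus III, 0.574 ± 0.01 with Callus II and 0.505 ± 0.013 with Callus I (mean and SD of 4 library pairs). Among callus types, II and III were the closest at 0.778 ± 0.024, then I and II at 0.714 ± 0.009 and I and III at 0.66 ± 0.008. These correlations are across genes, which are not independent replicates. The order of the callus types by correlation with leaf was found in 13 of 13 alternatives, but the values depend on the filter. With a mean of at least 5 FPKM the correlation with Leaf was 0.395 for Callus III, 0.349 for Callus II and 0.258 for Callus I, and with no filter it was 0.74, 0.711 and 0.659.

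The first principal component held 47.6% of the variance and placed Leaf at 184.72 and 183.61, Callus III at -5.79 and -12.37, Callus II at -56.78 and -66.12, and Callus I at -116.63 and -110.64. The next component (30.2%) set Callus I apart, with scores of 122.59 and 123.95, from Callus II (-75.73 and -70.58) and Callus III (-96.23 and -97.82). The third (19.3%) separated Callus III, at 108.98 and 84.0, from Callus II, at -101.93 and -101.85. The fourth held 1.2%.

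**Figure D1:**
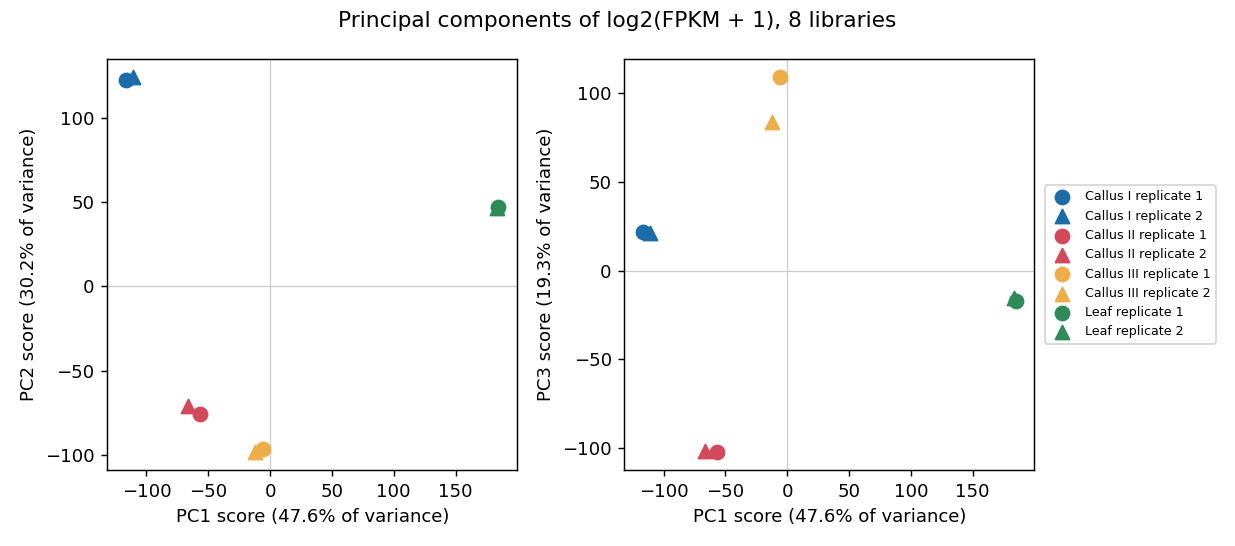
Scores of the 8 libraries on the first 3 principal components of log2(FPKM + 1), with the share of variance on each axis, colour for the group and shape for the replicate. Replicates lie together, and on the first component Leaf (184.72 and 183.61) is followed by Callus III (-5.79 and -12.37), Callus II and Callus I.

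A few abundant genes took a larger part of the FPKM sum in Callus III than elsewhere. The 10 highest genes held 25.13% and 23.78% of the FPKM sum in Callus III, 16.2% and 12.46% in Callus I, 17.27% and 7.77% in Callus II, and 6.83% and 9.28% in Leaf. The 100 highest held 44.02% and 39.35% in Callus III against 19.78% to 28.68% in the other 6 libraries. FPKM weights short loci, so these are not shares of reads. A locus of 264 bp, Sobic.002G206750.v3.2, chosen after its values were seen, alone held 9.5% of the sum in Callus II replicate 1 and 0 in replicate 2, and 4.24% and 0 in Callus I. Without loci under 500 bp, the 10 highest genes held 17.74% and 13.4% in Callus III, 8.08% and 8.57% in Callus I, 7.29% and 7.58% in Callus II, and 4.71% and 5.25% in Leaf. Median-ratio scaling factors were 1.207 and 1.2025 in Callus II and 0.8176 and 0.9413 in Callus III. They were 0.9619 and 0.948 in Callus I and 0.9912 and 0.9793 in Leaf. This scaling moved the median log2 difference of all genes from 0.18 to 0 for Callus II minus Callus I. For Callus III minus Callus I it moved from -0.031 to 0.019, and for Callus III minus Callus II from -0.33 to 0. Leaf minus Callus II moved from -0.109 to 0.064, and Callus II minus the mean of the other callus types from 0.237 to -0.04. For this reason, numbers of higher and lower genes and runs are given with the deposited FPKM and with median-ratio scaling. Median-ratio scaling sets the typical gene to no change, so a nearly even split of calls follows from it, and splits with equal sums of FPKM without the 100 highest genes are given as well. For equal sums, the 100 genes are 1 set for all libraries, those with the highest value in any library, unlike the 100 highest of each library above. Equal sums even out the genes outside that set, so they can also reduce a broad shift.

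**Figure D2:**
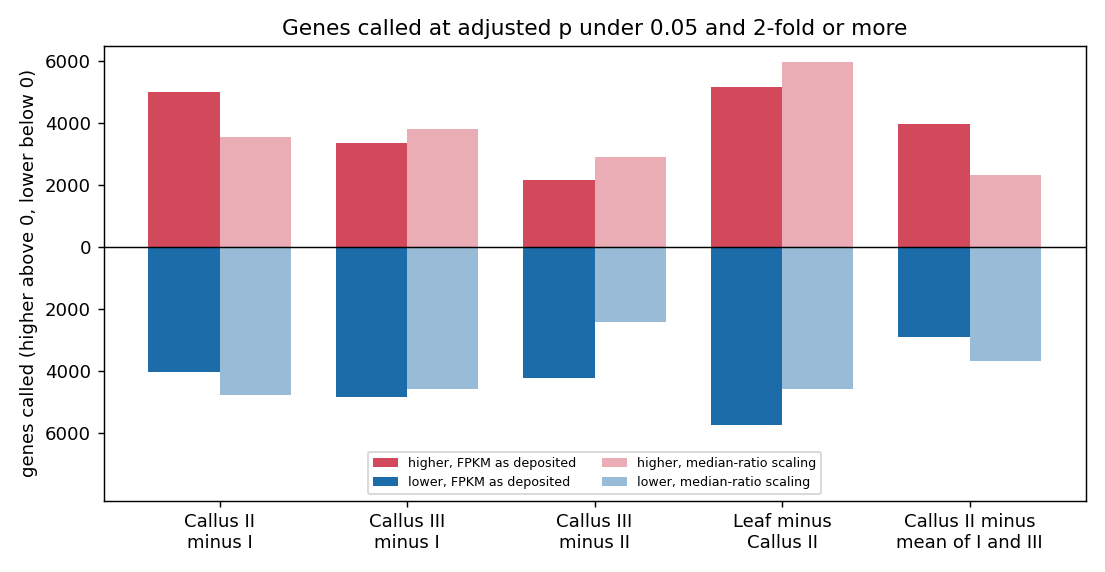
Number of genes called by limma at an adjusted p under 0.05 with a change of at least 2-fold, for each comparison, higher genes above 0 and lower genes below, with the FPKM as deposited in dark bars and after median-ratio scaling in pale bars. In Callus III minus Callus II the deposited values give 2170 higher and 4234 lower genes, and the scaled values give 2904 and 2434.

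Callus II and Callus I, which grew from the same kind of explant on the same medium, differed in a majority of the genes tested. In Callus II, Sobic.003G350400.v3.2 (chromosome 3, 67005652 to 67006780) was higher by 10.03 ± 0.28 on the log2 scale (SE, n = 2 per group; limma, Benjamini-Hochberg adjusted p = 2.09e-06). It stood at 1761 and 2441 FPKM in Callus II, 1.211 and 0.769 in Callus I, 306.8 and 501.6 in Callus III, and 3.60 and 5.17 in Leaf. Sobic.009G208700.v3.2 (chromosome 9, 55583465 to 55584955) was higher by 9.13 ± 0.4 (limma adjusted p = 5.58e-06), at 676 and 819 FPKM in Callus II against 0.543 and 0.144 in Callus I.

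In the other direction, Sobic.003G027000.v3.2 (chromosome 3, 2350633 to 2360561) had 532 and 298.5 FPKM in Callus I and 0.329 and 0.218 in Callus II, a log2 difference of -8.29 ± 0.32 (limma adjusted p = 3.96e-06). Its values in Callus III were 1.134 and 2.377 FPKM and those in Leaf 0.28 and 0.436. Sobic.009G055300.v3.2 (chromosome 9, 5577715 to 5579825) was lower by -8.07 ± 0.41 (limma adjusted p = 9.59e-06), at 746.6 and 388.4 FPKM in Callus I and 0.876 and 1.15 in Callus II.

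Whole stretches of chromosome carried transcripts in Callus I and next to none in Callus II. The run with the most genes was on chromosome 7 from 7229329 to 7504361 (275.0 kb), where 13 neighbouring tested genes were all lower in Callus II, by -3.98 to -1.69 with a median of -3.11. The median was -2.45 without Callus I replicate 1 and -3.69 without replicate 2. The median of these genes was 12.37 and 5.0 FPKM in the Callus I libraries and at most 0.11 in each of the other 6. Under the filter of a mean of at least 5 FPKM, 1 of the 13 was called. On chromosome 5, 8 neighbours from 10991903 to 11143061 (151.2 kb) had medians of 28.17 and 21.53 FPKM in Callus I and at most 0.08 elsewhere, with a median log2 difference of -4.16. Loci overlapping another made up 3 of those 8, and 5 were called under that filter. Higher in Callus II were 6 neighbours on chromosome 3 from 73983537 to 74062742, with medians of 17.77 and 16.78 FPKM against 1.94 and 0.48 in Callus I. Their median log2 difference was 3.6, and that of the stretch with no filter on low values was 1.06. A further 7 neighbours on chromosome 4 from 62680455 to 62819666 were higher, with medians of 17.88 and 16.28 FPKM against 4.91 and 4.54.

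In all, limma called 14936 of 23166 genes (64.5%) between Callus II and Callus I at an adjusted p under 0.05, 9062 higher and 5874 lower in Callus II. With median-ratio scaling 6945 were higher and 7473 lower, and with equal sums 8859 were higher and 6006 lower. Higher genes thus made up 60.7%, 48.2% and 59.6% of the calls. A change of at least 2-fold was found for 9069 genes, 5022 higher and 4047 lower, and this split turned with median-ratio scaling, to 3556 higher and 4780 lower. At 8-fold or more 656 were higher and 946 lower, and 531 and 1105 after scaling. Runs of neighbours numbered 44, 16 higher and 28 lower, with 250 genes in them, against a mean of 11.9 and a highest of 23 in 1000 shuffled orders. The longest run in those orders had 11 genes, so only the run of 13 genes was longer. The scaled values gave 8 higher and 39 lower runs, and a pseudocount of 0.1 FPKM gave 47 and 42, so the direction of runs depended on the setting. Among genes with a mean of at least 5 FPKM there were 17 runs, within the range of shuffled orders (highest 18).

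**Figure D3:**
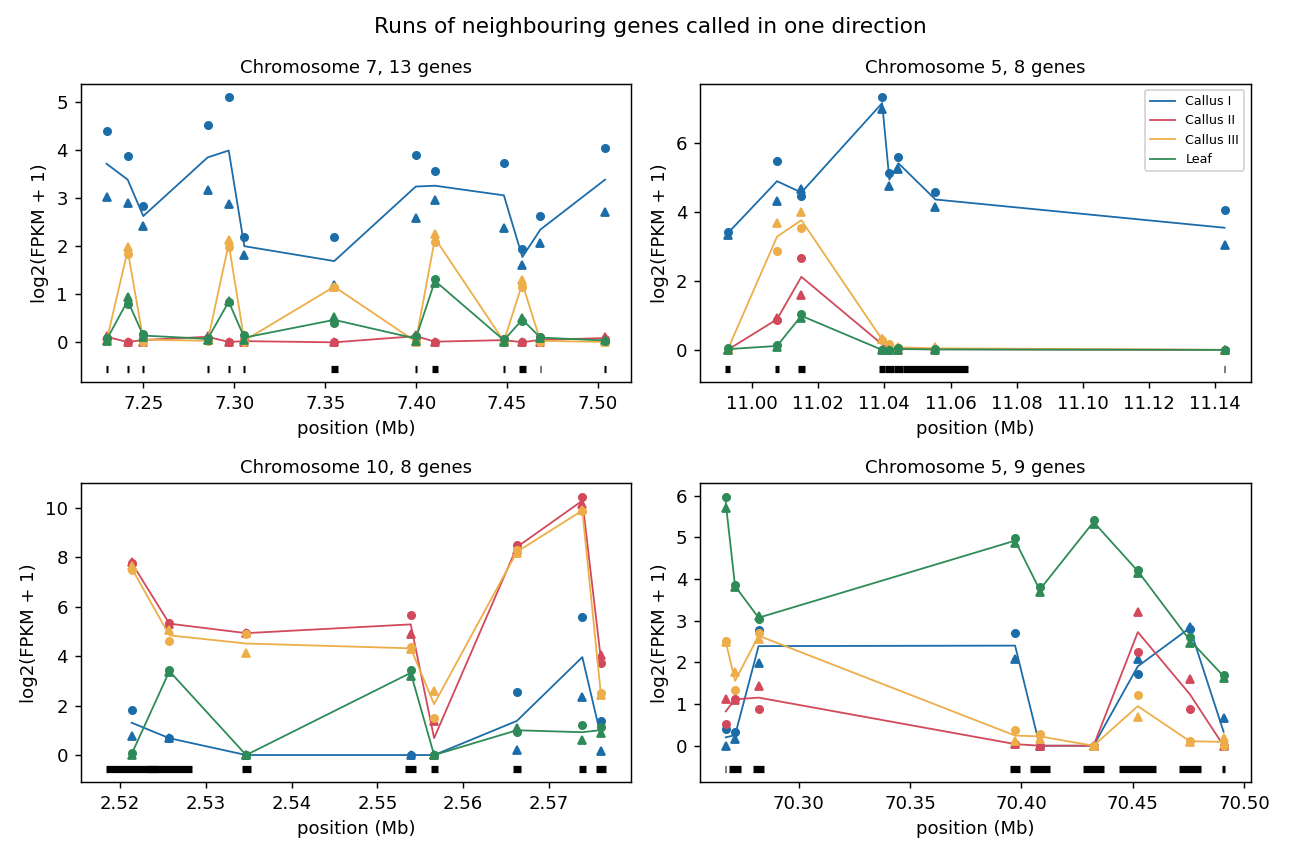
Expression along 4 runs of neighbouring genes, as log2(FPKM + 1) against position in Mb, with points for the 8 libraries (circles replicate 1, triangles replicate 2), lines for group means and black bars for loci. The 13 genes on chromosome 7 and the 8 on chromosome 5 near 11 Mb are highest in Callus I, the 8 on chromosome 10 are higher in Callus III than in Callus I, and the 9 on the other stretch of chromosome 5 are higher in Leaf than in Callus II.

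Among the genes that set Callus III apart from Callus I were 2 of extremely high abundance in Callus III. Sobic.007G075301.v3.2 (chromosome 7, 8648504 to 8649372) reached 22790 and 11430 FPKM in Callus III and was listed at 0 in all 6 other libraries (limma adjusted p = 4.8e-07, no fold given). Sobic.005G165700.v3.2 (chromosome 5, 64214230 to 64216294) reached 11890 and 9325 FPKM in Callus III, was at most 0.138 in any other library, and was higher than in Callus I by 13.26 ± 0.15 (SE; limma adjusted p = 1.61e-07).

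Callus I in turn expressed Sobic.007G158600.v3.2 (chromosome 7, 59287251 to 59289657) at 604.3 and 707.7 FPKM, against 0.262 and 0.382 in Callus III. The log2 difference was -8.95 ± 0.21 (limma adjusted p = 5.95e-07). Sobic.005G050200.v3.2 (chromosome 5, 4770080 to 4771218) stood at 659 and 1078 FPKM in Callus I, 125.2 and 40.01 in Callus II, 1.05 and 4.08 in Callus III, and 775 and 798 in Leaf. Callus III minus Callus I was -8.03 ± 0.6 (limma adjusted p = 3.92e-05), with -7.38 and -8.69 when Callus III replicate 1 or replicate 2 was left out.

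A block of 8 neighbouring genes on chromosome 10, from 2518319 to 2576676 (58.4 kb), was higher in Callus III than in Callus I by a median of 4.41 on the log2 scale. Its median was 26.15 and 25.46 FPKM in Callus III, 44.23 and 34.0 in Callus II, 1.08 and 0.14 in Callus I, and 1.03 and 0.71 in Leaf. Loci overlapping another made up 2 of the 8. Also higher in Callus III were 6 neighbours on chromosome 7 from 57321656 to 57400833, with medians of 8.36 and 10.76 FPKM against 0.51 and 0.21. Lower in Callus III than in Callus I were 7 neighbours on chromosome 3 from 72292483 to 72333246, with medians of 2.98 and 3.25 FPKM against 35.57 and 28.87. Callus II had 3.62 and 2.88 there and Leaf 1.52 and 1.21. The same held for 7 neighbours on chromosome 1 from 60163256 to 60360198, with medians of 3.81 and 2.61 against 47.7 and 47.55. Callus II had 2.81 and 6.11 there and Leaf 6.27 and 4.89. Both stretches were thus high in Callus I alone, and runs from the same starts were lower in Callus II than in Callus I. The 7 genes on chromosome 1 had a median log2 difference of -3.44, and that of their stretch with no filter on low values was -1.34.

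Between Callus III and Callus I, limma called 13930 genes (60.1%), 6236 higher and 7694 lower in Callus III. Median-ratio scaling gave 7227 higher and 7206 lower. With equal sums of FPKM after the 100 highest genes were left out, 56.3% of calls were higher, against 44.8% with the deposited values. At 2-fold or more, 3376 genes were higher and 4863 lower, and 3816 and 4605 after median-ratio scaling. The 46 runs, 6 higher and 40 lower (14 and 37 after scaling), exceeded the highest of the shuffled orders (18), as did the 17 runs among genes with a mean of at least 5 FPKM (highest shuffled 14). Shuffled orders gave a mean of 9.0 runs. The longest observed run had 8 genes, while shuffled orders held runs of up to 10, so no single run stood out by length. Some of the lower runs lie on stretches that were also lower in Callus II than in Callus I. Both comparisons use the same Callus I libraries, so such runs are not separate results.

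Callus III and Callus II, the callus types with the highest correlation, still differed by very large amounts at some genes. Sobic.008G030900.v3.2 (chromosome 8, 2751929 to 2760254, overlapping another locus) stood at 24960 and 20700 FPKM in Callus III and at 0.091 and 0.101 in Callus II, a log2 difference of 14.34 ± 0.73 (SE; limma adjusted p = 1.92e-05). It was also abundant in Leaf, at 3773 and 4559 FPKM, and present in Callus I at 161.2 and 24.67. Sobic.007G075301.v3.2, listed at 0 in Callus II, was the other gene at the top of the order (limma adjusted p = 5.17e-07). Callus II was alone in its high level of Sobic.005G080600.v3.2 (chromosome 5, 10617467 to 10619454), at 267.5 and 178 FPKM against 0.13 and 1.04 in Callus III, with a log2 difference of -7.17 ± 0.31 (limma adjusted p = 8.84e-06). Its values were 0.157 and 0.213 FPKM in Callus I and 0.0744 and 0.135 in Leaf.

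Sobic.004G311000.v3.2 (chromosome 4, 64749515 to 64752467) had 106.5 and 114.4 FPKM in Callus II, 0.151 and 0 in Callus III, 0.2625 and 0.341 in Callus I, and 0.553 and 0.575 in Leaf. Its log2 difference was -6.7 ± 0.14 (limma adjusted p = 5.38e-07). On chromosome 1, 5 neighbours from 69919640 to 69935701 (16.1 kb) were expressed in Callus III, with medians of 8.36 and 15.06 FPKM, while their medians in the other 6 libraries were at most 0.02. Of the 5, 3 were called under the filter of a mean of at least 5 FPKM. Another 7 neighbours on chromosome 1, from 68610741 to 68690338, were higher in Callus III than in Callus II by a median of 2.72. Their medians were 65.08 and 85.17 FPKM in Callus III and 12.69 and 15.68 in Callus II. With 74.27 and 34.25 in Callus I and 3.94 and 4.94 in Leaf, they were not high in Callus III alone. Just before them, 8 neighbours from 68265982 to 68441763 were lower by a median of -2.25, at 2.64 and 4.27 FPKM against 16.95 and 19.2 in Callus II. With no filter on low values the median of that stretch was -1.36. On chromosome 4, 8 neighbours from 64536411 to 64607186 were lower by a median of -1.79, and 5 of them were called under that filter.

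Genes at 0 in both Callus II libraries and at 10 FPKM or more in both Callus III libraries numbered 118, and 12 showed the opposite. The latter count was 7 with median-ratio scaling, 25 without Callus III replicate 2 and 19 without either Callus II replicate. Limma called 13284 genes (57.3%) between Callus III and Callus II, 3495 higher and 9789 lower in Callus III. Median-ratio scaling gave 10648 calls, 5253 higher and 5395 lower, and equal sums gave 11067, 4513 higher and 6554 lower. Higher genes thus made up 26.3%, 49.3% and 40.8% of the calls, and the size of the excess of lower genes depended on the scaling. At 2-fold or more, 2170 were higher and 4234 lower, and this split turned with median-ratio scaling, to 2904 higher and 2434 lower. At 8-fold or more 551 were higher and 304 lower, and 661 and 191 after scaling. There were 22 runs, 5 higher and 17 lower, against a mean of 4.0 and a highest of 12 in shuffled orders. The longest observed run had 8 genes, and shuffled orders held runs of up to 10. Median-ratio scaling left 11 runs (highest shuffled 5), 7 higher and 4 lower, and equal sums left 13, 7 higher and 6 lower, so the excess of lower runs depended on the scaling. Without Callus III replicate 1 there were 13 runs, and among genes with a mean of at least 5 FPKM 6, within the shuffled range (highest 10).

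Leaves differed from the Callus II tissue that they had grown from in more genes than any pair of callus types did. Sobic.009G234600.v3.2 (chromosome 9, 57389228 to 57390570) reached 3652 and 4618 FPKM in Leaf, was listed at 0 in both libraries of Callus II and of Callus I, and stood at 0.465 and 0.639 in Callus III (limma adjusted p = 9.27e-08, no fold given). Sobic.008G030900.v3.2, which overlaps another locus, was higher in Leaf than in Callus II by 11.89 ± 0.73 (SE; limma adjusted p = 1.06e-05). Leaves had grown in light on differentiation medium, and callus had been induced in the dark on induction medium. Tissue, light and medium therefore cannot be told apart in this comparison.

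Of the genes that fell, Sobic.002G349300.v3.2 (chromosome 2, 71409007 to 71409180, 174 bp) was listed at 0 in both Leaf libraries and at 833.8 and 804.3 FPKM in Callus II (limma adjusted p = 2.97e-07). Callus I had 8647 and 4906 FPKM of it and Callus III 308.4 and 295.3. Sobic.010G032000.v3.2 (chromosome 10, 2573486 to 2574343) fell from 1376 and 1117 FPKM in Callus II to 1.33 and 0.542 in Leaf, a log2 difference of -9.36 ± 0.9 (limma adjusted p = 8.49e-05). It lies within the block of 8 genes on chromosome 10 and had 46.68 and 4.05 FPKM in Callus I and 916 and 967.6 in Callus III.

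On chromosome 5, 9 neighbours from 70266948 to 70491651 (224.7 kb) were higher in Leaf, with medians of 13.39 and 12.99 FPKM against 0.44 and 1.14 in Callus II, and 4 of them were called under the filter of a mean of at least 5 FPKM. On chromosome 1, 9 neighbours from 21509025 to 21568651 had medians of 3.36 and 3.14 FPKM in Leaf and at most 0.1 in the 6 callus libraries, and 1 of them was called under that filter. Lower in Leaf were 7 neighbours on chromosome 1 from 68314677 to 68445466, by a median of -2.47. These overlap the stretch that was lower in Callus III, and both comparisons use the same Callus II libraries, where the median was 20.1 and 21.13 FPKM. The 7 neighbours on chromosome 6 from 48935098 to 49015240 were lower by a median of -2.31, at 1.04 and 0.91 FPKM in Leaf against 17.31 and 18.91, and all 7 were called in 13 of 18 alternatives.

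Genes at 0 in both Callus II libraries and at 10 FPKM or more in both Leaf libraries numbered 273, and 48 showed the opposite. Limma called 16545 genes (71.4%) between Leaf and Callus II, 7509 higher and 9036 lower in Leaf. Median-ratio scaling gave 8975 higher and 7557 lower, and equal sums 8077 higher and 8404 lower. At 2-fold or more 5170 were higher and 5750 lower, and this split turned with median-ratio scaling, to 5967 higher and 4597 lower. At 8-fold or more 1368 were higher and 988 lower, and 1501 and 792 after scaling. The 76 runs exceeded the highest of 42 in shuffled orders (mean 26.2), and among genes with a mean of at least 5 FPKM there were 33 (highest shuffled 31). The longest observed run had 9 genes, and shuffled orders held runs of up to 11. The direction of the runs depended on the setting. Of the 76, 44 were higher and 32 lower, against 57 and 12 with median-ratio scaling, 58 and 77 with a pseudocount of 0.1 FPKM, and 8 and 25 at a mean of at least 5 FPKM. The estimated relative depth of the Leaf libraries, which rests on 22.0% and 26.6% of low pairs, was 1.27 and 1.625 against 1.075 and 0.973 in Callus II.

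Callus II, the type that gave the leaves, was also set against the mean of the other callus types. Sobic.005G080600.v3.2 was higher in Callus II by 7.35 ± 0.27 (SE; limma adjusted p = 7.4e-06) and Sobic.009G208700.v3.2 by 6.75 ± 0.34 (limma adjusted p = 1.78e-05). The latter had 21.92 and 55.06 FPKM in Callus III and 0.63 and 0.337 in Leaf. Neither gene that led the rise in Callus II was thus abundant in the leaves grown from it. Sobic.008G030900.v3.2 was lower in Callus II by -10.11 ± 0.64 (limma adjusted p = 3.53e-05), with -9.45 and -10.78 when Callus I replicate 1 or replicate 2 was left out. Sobic.003G081900.v3.2 (chromosome 3, 7023283 to 7024065) was lower by -7.14 ± 0.24 (limma adjusted p = 6.25e-06), at 3.08 and 2.46 FPKM in Callus II, 119.9 and 186.5 in Callus I, 2355 and 1492 in Callus III, and 581 and 532 in Leaf.

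Limma called 14910 genes (64.4%) in this contrast, 9692 higher and 5218 lower in Callus II. Median-ratio scaling gave 6163 higher and 7370 lower, and equal sums 8105 higher and 5920 lower. Higher genes thus made up 65.0%, 45.5% and 57.8% of the calls. At 2-fold or more 3981 were higher and 2918 lower, and this split turned with median-ratio scaling, to 2330 higher and 3701 lower.

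Chromosome 5 held the highest share of changed genes in 3 of the 8 sets of genes changed by at least 2-fold in the 4 comparisons between pairs of groups, a comparison chosen after the values were seen. Of its 1249 tested genes, 22.2% were lower in Callus II than in Callus I, against 15.5% to 19.7% on the other chromosomes. For Callus III against Callus I, 26.7% of its genes were lower (17.8% to 23.1% elsewhere), and 28.4% were higher in Leaf than in Callus II (19.9% to 23.8% elsewhere). In 1000 random rotations of the gene order, a chromosome reached such a share with a permutation p of 0.033, 0.033 and 0.043. After Benjamini-Hochberg adjustment over the 8 sets the p was 0.115 for each, so chromosome 5 did not stand out beyond the threshold.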

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

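The runs of neighbours, loci of at least 500 bp, equal sums, scaling together with a fold threshold and shares without short loci were chosen after the data were seen. All 359 values of named genes under the alternatives kept their direction and call. Sobic.002G349300.v3.2, at 174 bp, has no value with loci of at least 500 bp only, so that alternative did not check it. These genes were picked for the largest changes in the same data, so their stability does not speak for typical calls. Of 100 counts of called genes under the alternatives, 87 lay within 1.5 times the reported count. The other 13 came with fewer genes or a stricter rule. In the order Callus II minus Callus I, Callus III minus Callus I, Callus III minus Callus II, Leaf minus Callus II, and Callus II minus the mean of the others, a 2-fold change left 9069, 8239, 6404, 10920 and 6899 genes, and together with median-ratio scaling 8336, 8421, 5338, 10564 and 6031. A mean of at least 5 FPKM left 9938, 10816 and 9880 in the comparisons of Callus II with Callus I, Leaf with Callus II, and Callus II with the mean. Leaving out each library in turn, with the lone sample assumed to vary like the other groups, gave 12668 to 15035, 12480 to 13428, 9985 to 14213, 13660 to 17224 and 11881 to 15193. Runs in the 4 pairwise comparisons numbered 89, 81, 36 and 135 with a pseudocount of 0.1 FPKM, 27, 24, 13 and 41 with no filter (more neighbours with low values between the genes), and 17, 17, 6 and 33 at a mean of at least 5 FPKM. For Callus III minus Callus II they numbered 11 with median-ratio scaling, 13 with equal sums and 13 to 24 with each library left out. The cause was not tested. Of the 78 mean correlations 18 moved by more than their SD, and over all alternatives those of Leaf ran from 0.258 to 0.659 with Callus I, 0.349 to 0.711 with Callus II and 0.395 to 0.74 with Callus III. Of 40 counts of genes at 0 in one group and at 10 FPKM or more in the other, 13 moved by over 1.5 times. The gene list tests were not run. Depth limits genes near 0 FPKM.

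With the replicate block, the counts were 14583, 13487, 12695, 16252 and 14521. The labels share replicate numbers between groups without saying that they mark a common day or culture, and the deviations of same-numbered libraries from their group means correlated at -0.103 to 0.018.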

Other observations

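The tests on the median shift between Callus III and Callus II and on genes that differ between Leaf and Callus I were chosen only after those results were seen. The test on short loci was chosen after 1 such locus had been seen.

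Genes that were higher in leaf than in Callus I lay above other genes in the difference between Callus III and Callus II. The 5816 genes called at least 2-fold higher in Leaf than in Callus I had a median Callus III minus Callus II value of -0.019 on the log2 scale. The median of all genes was -0.33, and 10000 random lists matched on mean expression gave -0.303 to -0.263. With these deposited values 42.9% of the 5816 genes were higher in Callus III, so most were lower there, by less than genes in general. With median-ratio scaling the median was 0.089, against -0.004 to 0.0 for random lists, and 58.0% of these genes were higher in Callus III. The 5117 genes lower in Leaf than in Callus I went the other way, with a median of -0.414 (1000 random lists -0.347 to -0.303) and of -0.104 with median-ratio scaling. Across genes, the 2 differences correlated at 0.165 and 0.153 under the 2 scalings, which is weak, and genes are not independent replicates. The fit that chose these lists shared its variance and filter with the Callus II and III libraries. Chosen instead on the 4 Leaf and Callus I libraries alone, the 5804 genes higher in Leaf had the same medians of -0.019 (random lists -0.296 to -0.258) and 0.089 (0.0 to 0.0). Whether these genes were higher in Callus III than in Callus II thus depends on the scaling. Their place above other genes was found under both. Scaling changes all genes of a library by the same factor, so the 2 results are not separate tests. With the deposited values, the log2 scale used here understates the general difference between Callus III and Callus II for genes with low values in callus. How far this adds to their place above other genes was not tested.

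Most genes lay lower in Callus III than in Callus II, by a median of -0.33. With the deposited values the median was 0.18 for Callus II minus Callus I and -0.031 for Callus III minus Callus I. With equal sums these were 0.155 and 0.115. The values thus do not place the shift in Callus III rather than in Callus II. A Callus III library that deviates alone is argued against, because the median stayed at -0.261 or -0.396 with either Callus III library left out. It was -0.323 or -0.334 with either Callus II library left out. Equal sums without the 100 highest genes brought the median to -0.097. That scaling evens the sum of all other genes, so it would shrink a broad difference of any cause. A larger share for a few abundant genes therefore stays possible but cannot be told apart from such a difference. The cause of the shift stays open, and no biological explanation was tested.

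Neighbouring genes changed together in each of the 4 comparisons between pairs of groups, with correlations of log2 differences between adjacent genes of 0.143, 0.135, 0.114 and 0.12 against at most 0.024 in 1000 shuffled orders. Overlapping loci that share reads are argued against as the whole cause, because without them the lowest correlation was 0.099 (shuffled at most 0.023). Closely spaced genes alone are argued against too, because adjacent genes over 10 kb apart gave at least 0.062 (shuffled at most 0.041). The correlation was smaller over that distance, so close spacing may add to it. Tandem copies that share reads over longer distances and regulation by chromosome domain stay open, and no biological explanation was tested.

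At 57 loci a value of 0 in one replicate stood beside at least 5 FPKM in the other. Sobic.002G206750.v3.2 (chromosome 2, 59828774 to 59829037, 264 bp) is an example, chosen after its values were seen, with 67669 FPKM (9.5% of the sum) in Callus II replicate 1 and 0 in replicate 2. Loci under 500 bp made up 27 of the 57 (47.4%) against 220 of 18712 others (1.2%), a ratio of 40.29 (Fisher's exact test, 2-sided p = 3.9e-36), so a failed FPKM estimate at short loci may account for these 27. The length is that of the whole locus and not of the transcript, so the other 30 stay open. Overlap with another locus is argued against, at 14.0% against 11.7%, a ratio of 1.2 (Fisher's exact p = 0.54). No biological explanation was tested.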
